A study of Homo sapiens with 4 samples.

How the data were processed

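RNA sequencing libraries were made from 1 µg of total RNA with the TruSeq V2 kit, per the labels' protocols, from cells of a human renal carcinoma line grown in DMEM with 10% fetal bovine serum and starved of amino acids for 12 h. There were 2 libraries with a non-targeting hairpin (shNT) and 2 with a hairpin against GLUD1 (shGLUD1), grouped by the sample titles. The authors deposited one table of TPM (transcripts per 1000000) with 57820 genes, named by Ensembl identifier and symbol, and 1 column per library. Each column summed to 1000000 and was written to 2 decimals, so TPM were scaled within each library, and no scaling between libraries was seen. The submitters' processing notes list Bowtie 0.12.2 and the builds hg38 and mm8 without saying what each was used for; the quantifier, the annotation and any filter are not given in the sources used here. TPM divide each gene by the library's total, so a fall in a few abundant transcripts raises all others, and they keep no read totals: depth per library is unknown, and no counting interval or detection floor can be given.

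Values were analysed as log2(TPM + 1), so fold changes are on that scale and understate the change of low genes. Genes with a mean of at least 1 TPM over the 4 libraries were kept (12524). The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), group as the only term, and Benjamini-Hochberg adjusted p under 0.05 as the threshold; all tests were two-sided. Gene lists (33, with 1045 entries, of which 1044 were found in the table) were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, for the 31 lists with at least 5 measured genes, adjusting over those lists. With 2 libraries per group the version with an estimated correlation has few degrees of freedom and little power. A call absent there is no evidence against a list. Each list was also counted by members higher and lower, adjusted over all genes and over the list alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, rank correlations and figures.

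Coordinates, gene types, transcript lengths (longest coding transcript, otherwise the longest) and GC content came from GENCODE release 29 on GRCh38, matched by gene identifier: 52338 of the 57820 identifiers matched, and 97.9% of the genes tested had a length. Symbols are those of the table; 51996 identifiers matched a current gene name. TXNIP and 1 of the 2 UQCR11 entries are listed under identifiers that carry no current name. The grouping, test, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took GLUD1 and GLUD2, the 12 largest increases and 12 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 TPM, non-overlapping groups and a symbol that is not a clone, non-coding RNA or pseudogene name, and up to 4 passing members of each list with the largest change, or the 2 with the smallest p where fewer than 2 passed. In total 138 genes were chosen this way, of which 4 are not reported here; others are said to have been chosen after their values were seen.

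The alternatives fixed in advance were a pseudocount of 0.1 TPM, no filter on low values, a mean of at least 5 TPM, median-ratio rescaling of the libraries, quantile normalization, limma without a variance trend, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, and fry. Added after seeing the data were removal of trends with transcript length and GC content (a loess fit per library), protein-coding genes only, and leaving out the cytosolic ribosomal protein genes, the last 2 with TPM set to 1000000 over the genes left. Median-ratio factors differed between groups (log2 -0.38 and -0.37 for shNT, 0.29 and 0.50 for shGLUD1), so rescaled values are given beside TPM. The fit was tested on simulated data for the comparison of shGLUD1 with shNT, with 200 genes changed in each of 5 runs and 11188 to 11236 genes passing the filter. Among these, 458 of 476 genes changed 2-fold (96.2%) and 464 of 464 changed 4-fold (100%) were recovered, with 5 to 12 false calls per run. With none changed and 11206 to 11247 genes, 5 runs gave 0 false calls. The simulated noise was independent between genes, with no shift common to most genes and no trend with length or GC content. The real libraries had both, so these rates do not give the error rates of the comparison below.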

Results

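RNA was sequenced from cells of an established human renal carcinoma line carrying either a non-targeting short hairpin RNA (shNT) or a hairpin against GLUD1 (shGLUD1). GLUD1 encodes the mitochondrial glutamate dehydrogenase, which converts glutamate to alpha-ketoglutarate and ammonia. All 4 libraries came from cells starved of amino acids for 12 h, 2 libraries per hairpin, so the one comparison is between hairpins under starvation and no fed cells were compared. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Limma also borrows that spread across genes (median prior of 8.8 degrees of freedom). A small p or SE therefore does not rest on a gene's own libraries alone. The table holds TPM values, which keep no read totals, so the sequencing depth is unknown. Genes above 0 numbered 19724 and 19958 in the shNT libraries and 20137 and 20489 in the shGLUD1 libraries. All means below are given ± SD with n = 2 libraries per group.

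The targeted gene was read first. GLUD1 (ENSG00000148672, GRCh38 chromosome 10, 87050486 to 87094866, minus strand, protein-coding) stood at 18.1 and 17.4 TPM in the shNT libraries and at 13.5 and 19.8 TPM in the libraries labelled shGLUD1, so replicate 2 of the labelled knockdown was above both controls. The log2 fold change was -0.11 (SE 0.19, limma adjusted p = 0.631). After median-ratio rescaling, which sets the typical gene to no change, GLUD1 was lower by a log2 fold change of -0.83 (SE 0.15, limma adjusted p = 0.00233). Without shGLUD1 replicate 1 the unrescaled value was 0.15. GLUD2, a near-identical copy on chromosome X, was listed at 0.15, 0.02, 0.03 and 0.2 TPM in the same order of libraries. Because GLUD1 TPM was not lower in 1 of the labelled libraries, shGLUD1 below means libraries labelled shGLUD1, and each direction is drawn from that label.

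The comparison asks which transcripts differ in starved cells when GLUD1 is targeted. In shGLUD1, 9 of 14 heat shock genes fell and 1 rose on TPM (13 lower and none higher after median-ratio rescaling), 15 of 38 ATF4 targets fell and 11 rose (28 lower and 4 higher rescaled), and all 34 mitosis genes rose (29 higher and none lower rescaled). HSPA6, a stress-inducible member of the HSP70 chaperones, was at 852 ± 99 TPM in shNT and 2.94 ± 0.8 TPM in shGLUD1 (log2 fold change -7.77, SE 0.15). DDIT3, the stress transcription factor CHOP, was at 713 ± 15.8 TPM in shNT and 124 ± 15.4 TPM in shGLUD1 (-2.52), and SLC3A2, the heavy chain of several amino acid transporters, was at 769 ± 0.83 TPM in shNT and 117 ± 8.1 TPM in shGLUD1 (-2.71). In the other direction, EGFR, the epidermal growth factor receptor, was at 22.4 ± 3.2 TPM in shNT and 416 ± 93.4 TPM in shGLUD1 (4.14, SE 0.16), and TPX2, a spindle assembly factor, was at 6.83 ± 0.45 TPM in shNT and 60.8 ± 11.7 TPM in shGLUD1 (2.97). All 5 passed the limma test, with adjusted p between 4.5e-10 and 9.6e-07, and the rescaled values of EGFR and TPX2 were 3.39 and 2.26.

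Of 12524 genes tested by limma-trend, 8078 changed at an adjusted p under 0.05, 7105 of them higher and 973 lower in shGLUD1, and 3921 changed at least 2-fold (3698 higher, 223 lower). The median of all genes tested was itself 0.63 log2 units higher in shGLUD1, 1.54-fold on TPM + 1, which understates the shift in TPM. Median TPM of these genes was 5.77 and 5.885 in the shNT libraries and 9.82 and 11.6 in the shGLUD1 libraries. Rescaled so that the median gene did not move, 6401 genes changed, 2910 higher and 3491 lower, and 2084 changed at least 2-fold. Of the genes higher on TPM, 2910 remained higher and 234 were then lower. Rescaling lowers nearly all fold changes alike, so the 973 lower on TPM stayed lower by construction, which says nothing of their stability. Directions below are therefore given on TPM and, as the rescaled value, relative to the median gene. Pearson r of log2 values across genes was 0.989 within shNT, 0.985 within shGLUD1 and between 0.931 and 0.946 across groups, where genes are not independent replicates. On unrescaled TPM the groups did not overlap in 10446 genes, 83.4% of those tested, against 33.3% by chance for 2 against 2. The shift of the median gene can by itself separate many genes, and all genes share the same 4 libraries. The excess over 33.3% is therefore no evidence on single genes. For a single gene tested alone, an exact permutation of 2 against 2 cannot give a two-sided p below 0.333.

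**Figure D1:**
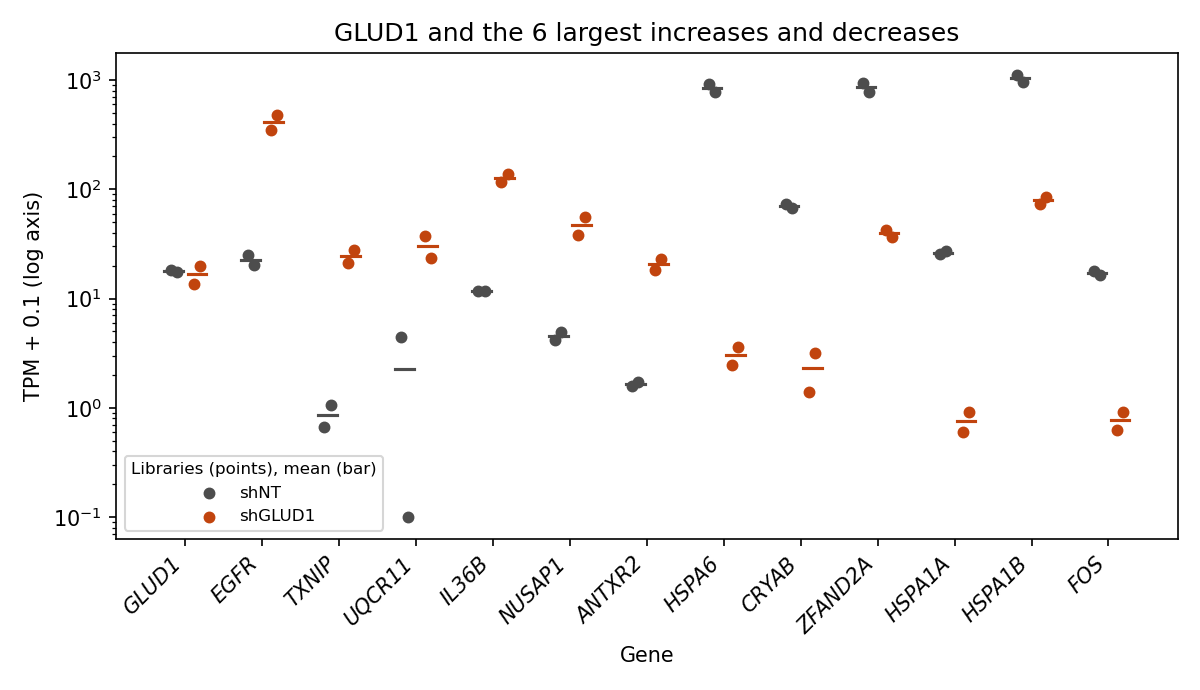
TPM plus 0.1 on a log axis for GLUD1 and for the 6 genes with the largest increase and the 6 with the largest decrease under the naming rule, one point per library and a bar at each group mean (n = 2 per group). The rule left out non-coding RNAs, some of which fell further than HSPA1A. GLUD1 overlaps between groups, EGFR rose from a mean of 22.4 to 416 TPM and HSPA6 fell from 852 to 2.94 TPM.

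Under the naming rule, which left out non-coding RNAs, the 12 largest increases among genes with a mean of at least 5 TPM included EGFR, TXNIP, which binds thioredoxin and restrains glucose uptake (0.765 ± 0.28 TPM in shNT and 24.5 ± 4.8 TPM in shGLUD1, log2 fold change 3.85), and IL36B, an interleukin-1 family cytokine (11.6 ± 0.021 TPM in shNT and 128 ± 15.8 TPM in shGLUD1, 3.34). NUSAP1, KIF20A, TPX2 and PRC1, which act on the mitotic spindle, rose by log2 fold changes of 3.12, 2.998, 2.97 and 2.86. CKAP5, a microtubule polymerase, rose by 3.07, NCAPD2, a condensin subunit, by 3.01, RRM2, the small subunit of ribonucleotide reductase, by 2.92, and ANTXR2, an anthrax toxin receptor, by 3.08. Rescaled values for these 11 genes lay between 2.14 and 3.39. A gene listed as UQCR11 under an identifier without a current name (ENSG00000267059) was at 4.34 and 0 TPM in shNT and 37.2 and 23.6 TPM in shGLUD1 (3.73, rescaled 3.20). Its log2 fold change ranged from 2.52 to 4.94 with each library left out in turn. It overlaps the established UQCR11 gene on the same strand, so how reads were split between the 2 is uncertain.

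Under the same rule, the 12 largest decreases held 4 genes of the heat shock response besides HSPA6. Among the non-coding RNAs left out, RMRP (-4.87), SNORD3A (-4.58) and RN7SK (-4.37), named after their values were seen, fell further than HSPA1A. CRYAB, a small heat shock protein, was at 69.9 ± 4.6 TPM in shNT and 2.2 ± 1.3 TPM in shGLUD1 (log2 fold change -4.53), and DNAJB1, an HSP40 co-chaperone, was at 1898 ± 114 TPM in shNT and 189 ± 21.4 TPM in shGLUD1 (-3.33). HSPA1B was at 1035 ± 107 TPM in shNT and 79 ± 7.6 TPM in shGLUD1 (-3.69) and HSPA1A at 26.3 ± 1.4 TPM in shNT and 0.66 ± 0.23 TPM in shGLUD1 (-4.04); these HSP70 genes are near-identical, so the split between them is uncertain. ZFAND2A, an arsenite-inducible gene, and HMOX1, the inducible heme oxygenase, had log2 fold changes of -4.41 and -2.70. FOS, an immediate early transcription factor, fell (-3.44), as did the growth arrest genes GADD45G and GADD45B (-3.25 and -2.61). DDIT3 and SLC3A2 complete the 12.

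Among 14 measured members of the heat shock list, 9 fell, 1 rose and 4 did not pass. The list median lay -1.66 log2 units from that of all genes (camera adjusted p = 9.2e-16; adjusted p = 0.486 with an estimated correlation). The 1 that rose was HSP90AB1 (0.63), a constitutive HSP90; it was chosen for naming after its values were seen, and its rescaled value was -0.13. After rescaling 13 were lower and none higher in the limma test. Of 22 genes of the unfolded protein response, 7 fell and 6 rose, with a list median -0.80 from all genes (camera adjusted p = 1.7e-05; 0.794 as the adjusted p with an estimated correlation). SDF2L1, an endoplasmic reticulum co-chaperone, fell (-1.07, rescaled -1.83). CANX, the lectin chaperone calnexin, rose (1.16, rescaled 0.41), as did EDEM1 and DNAJC3 (0.97 and 0.94), whose rescaled values of 0.34 and 0.40 did not pass. DNAJC3 also lost its call without shNT replicate 1 (0.79, 0.0959) or shGLUD1 replicate 2 (0.75, 0.0526), each value with its adjusted p. Rescaled, 17 were lower and 1 higher.

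Of 38 measured targets of ATF4, the transcription factor induced by amino acid shortage, 15 fell, 11 rose and 12 did not pass, and the list median lay -0.76 log2 units from all genes (camera adjusted p = 4.6e-10; adjusted p = 0.794 with an estimated correlation). Besides SLC3A2 and DDIT3, PPP1R15A, a phosphatase subunit that reverses eIF2alpha phosphorylation, was at 189 ± 18.3 TPM in shNT and 38.8 ± 5.3 TPM in shGLUD1 (-2.26), and TRIB3, a pseudokinase, was at 106 ± 0.41 TPM in shNT and 21.3 ± 2.3 TPM in shGLUD1 (-2.26). After rescaling 28 were lower and 4 higher. Against no change, the list was not called by fry (TPM median -0.13, adjusted p = 0.0825), and without a filter on low values its median lay -0.33 from all genes. Low genes added there lowered the median of all genes, while the list's own median stayed the same. Among 22 NRF2 targets, genes of the oxidative stress response, 6 fell and 8 rose (list median -0.33 from all genes, camera adjusted p = 0.0197; 0.794 as the adjusted p with an estimated correlation). HMOX1 fell from 769 ± 28.2 to 118 ± 10.3 TPM. AKR1C3, an aldo-keto reductase, rose (1.71, rescaled 1.03), and TXNRD1 and GCLM rose on TPM (1.04 and 0.95) with rescaled values of 0.30 and 0.27 that did not pass. GCLM also lost its call without shNT replicate 1 (0.65, 0.0937) or shGLUD1 replicate 2 (0.79, 0.0705), each value with its adjusted p. Rescaled, 12 NRF2 targets were lower and 1 higher. The NRF2 call was lost under quantile normalization (adjusted p = 0.31), without a filter on low values (0.206), at a mean of at least 5 TPM (0.0548) and without shGLUD1 replicate 1 (0.0525).

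Transcripts of the cytosolic ribosome were abundant and took a smaller share in shGLUD1. They took 31.9% and 32.3% of all TPM in the shNT libraries and 23.6% and 21.5% in the shGLUD1 libraries. Of 79 measured genes, 58 fell, 8 rose and 13 did not pass; adjusted over the list alone, 60 fell and 8 rose. The list median lay -1.04 log2 units from all genes (camera adjusted p = 4.4e-37; adjusted p = 0.486 with an estimated correlation). RPS27 was at 18892 ± 511 TPM in shNT and 8923 ± 1019 TPM in shGLUD1 (-1.09), and RPS29 and RPL30 fell (-1.09 and -1.03), whereas RPL14 rose (1.23, rescaled 0.47). RPL14 lost its call with trends in length and GC removed (limma adjusted p = 0.0563). Its assigned length was that of its longest coding transcript, 7072 nt, so the correction is too large if a shorter one was expressed. Relative to all genes, the list median was -0.29 under quantile normalization and -0.61 without a filter on low values. The latter came from a lower median of all genes, as the list's own median stayed the same. After rescaling 72 were lower and 1 higher.

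Genes of the mitochondrion were read as 3 lists. Of 75 mitochondrial ribosomal protein genes, 27 rose and 14 fell on TPM, 26 and 13 adjusted over the list alone, but 3 were higher and 55 lower after rescaling. Their median lay -0.53 from all genes (camera adjusted p = 0.00345; 0.486 as the adjusted p with an estimated correlation), although it was above 0 on TPM (0.10), and fry, which tests a list against 0, called it higher (adjusted p = 0.0357). It lay -0.18 from all genes under quantile normalization and -0.21 with length and GC trends removed. MRPL54 was at 699.6 ± 38.8 TPM in shNT and 263 ± 56 TPM in shGLUD1 (-1.42), and MRPL44, MRPS27 and MRPS31 rose on TPM (1.67, 1.60 and 1.19), the last with a rescaled value of 0.53 that did not pass. Of 77 nuclear genes of oxidative phosphorylation, 32 rose and 16 fell on TPM, and 7 were higher and 57 lower after rescaling (median -0.47 from all genes, camera adjusted p = 0.017; 0.486 as the adjusted p with an estimated correlation). Their largest changes were increases, in ATP5A1 (1.87, rescaled 1.11), NDUFS1 (1.81, 1.09), UQCRC2 (1.79, 1.04) and NDUFA9 (1.61, 0.89), subunits of ATP synthase and of respiratory complexes. Among the 13 mRNAs of the mitochondrial genome, 10 rose and 1 fell, and 7 were higher and 3 lower after rescaling (median 0.57 from all genes, camera adjusted p = 0.0285; 0.794 as the adjusted p with an estimated correlation). They held 0.369% and 0.341% of TPM in shNT and 0.687% and 0.641% in shGLUD1; MT-ATP8, MT-ND1, MT-ATP6 and MT-ND5 rose (2.35, 1.68, 1.66 and 1.63). MT-ATP8 and MT-ATP6 overlap, so their split is uncertain. Fry called the oxidative phosphorylation list higher (median 0.16 on TPM, adjusted p = 0.0357). The camera call was lost once length and GC trends were removed (adjusted p = 0.166), without a filter on low values (0.395) and without shNT replicate 1 (0.149), shNT replicate 2 (0.181) or shGLUD1 replicate 2 (0.118), and its median changed side under quantile normalization (0.034, adjusted p = 0.554). The call on mitochondrial mRNAs was lost after rescaling (0.198), without a variance trend (0.232), with ribosomal protein genes left out (0.0567) and without shGLUD1 replicate 1 (0.156) or replicate 2 (0.0925), and that on mitochondrial ribosomal proteins without a filter on low values (0.219).

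Cell cycle transcripts were higher. All 34 measured mitosis genes rose on TPM and 29 were higher, none lower, after rescaling, with a list median 1.04 log2 units above all genes (camera adjusted p = 5e-09; adjusted p = 0.794 with an estimated correlation). NUSAP1 was at 4.43 ± 0.5 TPM in shNT and 47 ± 12.6 TPM in shGLUD1, KIF20A at 1.2 ± 0.0071 TPM in shNT and 16.6 ± 2.8 TPM in shGLUD1, and DLGAP5, a spindle protein, rose by a log2 fold change of 2.85 (rescaled 2.27). Of 40 genes of S phase and DNA replication, 36 rose and none fell, 38 and none adjusted over the list alone, and 27 were higher and 1 lower after rescaling (median 0.69 above all genes, camera adjusted p = 5.7e-06; 0.794 as the adjusted p with an estimated correlation). RRM2 was at 9.21 ± 1.1 TPM in shNT and 78.1 ± 23.7 TPM in shGLUD1, and RRM1, the large subunit of the same enzyme, at 9.5 ± 0.78 TPM in shNT and 42.6 ± 11.6 TPM in shGLUD1 (2.03, rescaled 1.31). RFC3 and RFC4, subunits of the clamp loader of DNA replication, rose by 2.12 and 1.86. Replication-dependent histone mRNAs were not called as a list (27 measured, 8 higher, 3 lower, rescaled 4 and 7, camera adjusted p = 0.28), and HIST1H2BK, HIST2H2BE, HIST1H1C and HIST1H2AC rose (1.89, 1.51, 1.34 and 1.19).

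**Figure D2:**
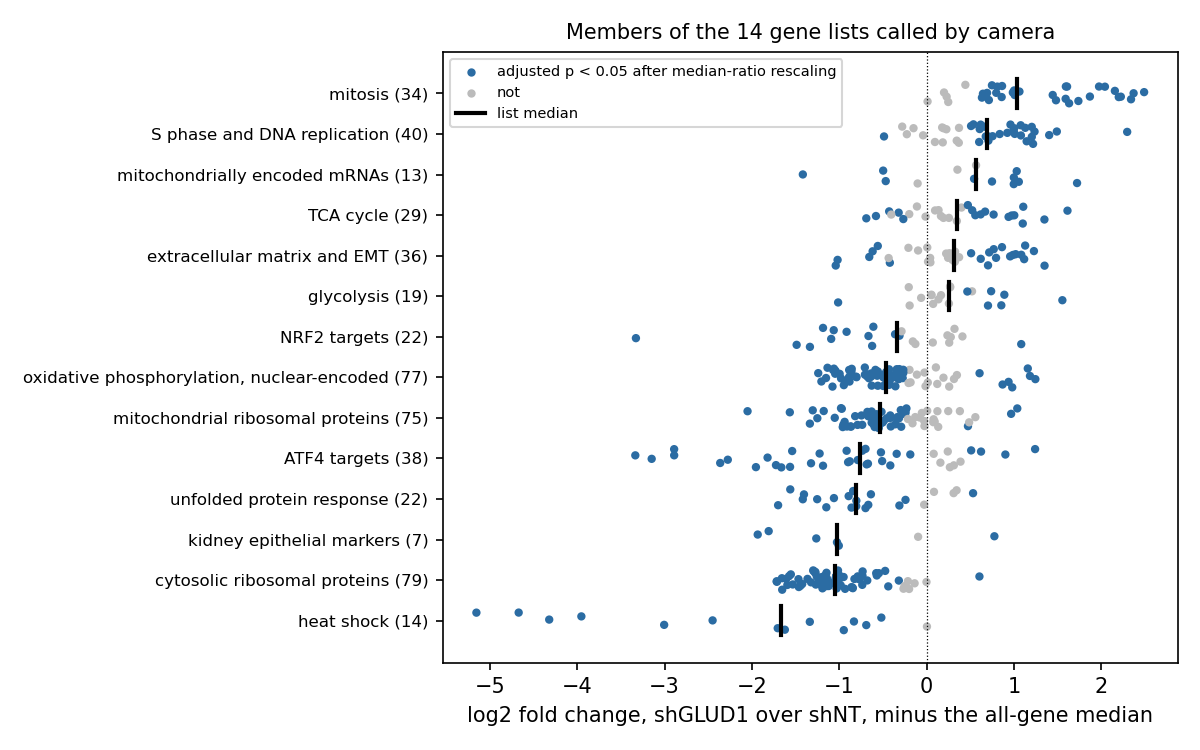
Log2 fold change of shGLUD1 over shNT minus the median of all genes tested, for each measured member (point) of the 14 gene lists called by camera; blue points passed at an adjusted p under 0.05 after median-ratio rescaling, and the black bar is the list median. Medians run from -1.66 for heat shock to 1.04 for mitosis. None of the 14 lists was called with an estimated correlation, a version with little power at 2 libraries per group.

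In central carbon metabolism, 18 of 19 glycolysis genes rose on TPM and 1, the glucose transporter gene SLC2A1 (-0.39, named after its values were seen), fell. The list median lay 0.26 above all genes (camera adjusted p = 0.00164; adjusted p = 0.794 with an estimated correlation). LDHA, lactate dehydrogenase A, was at 259 ± 11 TPM in shNT and 1187 ± 209 TPM in shGLUD1 (2.18, rescaled 1.42), and PFKM, PFKFB4 and HK1 rose (1.52, 1.48 and 1.37). Of 29 genes of the TCA cycle list, 25 rose and none fell (median 0.35 above all genes, camera adjusted p = 0.0029; 0.902 as the adjusted p with an estimated correlation), among them ACO1, DLD, OGDH and CS (2.24, 1.98, 1.73 and 1.73); ACO1 encodes the cytosolic aconitase. Rescaled, 6 glycolysis genes were higher and 1 lower, 13 TCA cycle genes were higher and 5 lower, and both camera calls were lost (adjusted p = 0.235 and 0.126). The glutamine, glutamate and proline list, to which the targeted step belongs, was not called (22 measured, 11 higher, 2 lower, rescaled 6 and 10, camera adjusted p = 0.795). Within it GOT2, the mitochondrial aspartate aminotransferase, was at 28.3 ± 2 TPM in shNT and 82.7 ± 14.1 TPM in shGLUD1 (1.504, rescaled 0.76), and CTPS1, GFPT1 and OAT rose (1.34, 1.32 and 1.29).

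Amino acid handling and translation genes moved in both directions. Of 18 amino acid transporters, 7 rose and 2 fell, and 3 were higher and 7 lower after rescaling (camera adjusted p = 0.0795). The largest change in this list was the fall of SLC3A2 (-2.71, rescaled -3.47). SLC1A1, a glutamate transporter, was at 2.25 ± 0.092 TPM in shNT and 10.9 ± 2.6 TPM in shGLUD1 (1.85, rescaled 1.23), and SLC38A1 and SLC38A2, glutamine transporters, rose by 1.35 and 1.14 and lost their calls with length and GC trends removed (adjusted p = 0.12 and 0.0629). The transporter list was called lower without shNT replicate 1 (camera adjusted p = 0.0236) or replicate 2 (0.0158), with length and GC trends removed (median -0.64 from all genes, 0.0231), for coding genes (0.0293) and without ribosomal protein genes (0.0457). Of 20 aminoacyl-tRNA synthetases, 16 rose and 1 fell, 17 and 1 adjusted over the list alone, and 6 were higher and 7 lower after rescaling (camera adjusted p = 0.052); FARSB, NARS, IARS and LARS rose (1.98, 1.90, 1.66 and 1.62). The synthetase list was called higher without shNT replicate 1 (camera adjusted p = 0.00829), shNT replicate 2 (0.0106) or shGLUD1 replicate 1 (0.0333), without a filter (0.00343) and under quantile normalization (0.025). Of 34 translation factors, 23 rose and 3 fell, 24 and 3 adjusted over the list alone, and 9 were higher and 13 lower after rescaling (camera adjusted p = 0.24), with EIF2S3, EIF1AX, EIF4E and EIF3A at 1.94, 1.90, 1.81 and 1.75. Camera called this list higher without shNT replicate 1 (adjusted p = 0.021) or replicate 2 (0.0118), without a filter (0.0298) and under quantile normalization (0.00047). Of 44 ribosome biogenesis genes, 26 rose and 2 fell, and 11 were higher and 17 lower after rescaling (camera adjusted p = 0.943); NCL, nucleolin, was at 50.1 ± 0.52 TPM in shNT and 182 ± 28 TPM in shGLUD1, and WDR75, NOLC1 and LYAR rose (1.70, 1.65 and 1.63).

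Lists of lipid synthesis and protein degradation were not called. Cholesterol genes numbered 16 higher and 1 lower of 23 (rescaled 4 and 6, camera adjusted p = 0.63), with SQLE and MSMO1 at 1.21 and 1.13. MSMO1 did not pass after rescaling (0.46, 0.0715 as the adjusted p), nor SQLE with length and GC trends removed (0.38, 0.079). Fatty acid synthesis genes numbered 11 higher and none lower of 16 (rescaled 3 and 4, camera adjusted p = 0.283), with ACSL4, ACLY, ACSL1 and FASN at 1.61, 1.25, 1.23 and 1.08. FASN did not pass after rescaling (0.34, 0.094 as the adjusted p), and ACSL1 and FASN did not with trends removed (0.30, 0.124 and 0.25, 0.138). Without a filter the fatty acid list was called higher (camera adjusted p = 0.0452). Of 44 lysosome and autophagy genes, 26 rose and 5 fell (rescaled 9 and 17, camera adjusted p = 0.943); NBR1, RRAGD and ATP6V1A rose (1.78, 1.66 and 1.64). Of 31 proteasome genes, 15 rose and 3 fell (rescaled 5 and 16, camera adjusted p = 0.943); PSMD1, PSMD12, PSMD2 and PSMD7 rose (1.53, 1.47, 1.31 and 1.17). The proteasome list was called in opposite directions by 2 scalings: lower after rescaling (camera adjusted p = 0.0368, median -0.46 from all genes) and higher under quantile normalization (camera adjusted p = 0.025, median 0.13).

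Of 36 extracellular matrix and epithelial-mesenchymal genes, 28 rose and none fell (median 0.31 above all genes, camera adjusted p = 0.00898; adjusted p = 0.902 with an estimated correlation), and 15 were higher and 6 lower after rescaling. VIM, the intermediate filament vimentin, was at 911 ± 28.4 TPM in shNT and 3329 ± 604 TPM in shGLUD1 (1.86, rescaled 1.09), and FBN1, LAMB1 and ZEB1 rose (1.98, 1.76 and 1.75). This call was lost after rescaling (0.0508), with length and GC trends removed (0.196) and without a variance trend (0.0554), each an adjusted p. In the interferon list, 21 of 33 rose and 7 fell, 22 and 7 adjusted over the list alone, and 13 were higher and 9 lower after rescaling (camera adjusted p = 0.989); HERC5, DDX60 and DDX58 rose (2.83, 1.89 and 1.82). Of 25 NF-kB and inflammatory genes, 12 rose and 6 fell, 13 and 6 adjusted over the list alone (rescaled 5 and 11, camera adjusted p = 0.0896). CXCL8 (listed as IL8), a neutrophil chemokine, was at 534 ± 33.6 TPM in shNT and 131 ± 14.5 TPM in shGLUD1, CXCL3 fell (-1.80), and CSF1 and TNFAIP2 rose (2.39 and 1.46). The list was called lower without shGLUD1 replicate 1 (camera adjusted p = 0.0489) and for coding genes (0.0363). Of 22 immediate early genes, 11 rose and 5 fell (rescaled 7 and 10, camera adjusted p = 0.283), with FOS and FOSB lower (-3.44 and -2.08) and CYR61 and FOSL1 higher (2.35 and 1.96).

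Targets of HIF, the hypoxia-inducible factor, numbered 16 higher and 4 lower of 24 (rescaled 8 and 7, camera adjusted p = 0.943). Among them BNIP3L, CA12, CA9 and CCND1 rose (2.12, 2.08, 1.53 and 1.41). Of 22 p53 targets, 15 rose and 1 fell (rescaled 2 and 6, camera adjusted p = 0.975). The 1 that fell was SESN2, a stress-induced sestrin that ATF4 also controls, at 46.6 ± 0.39 TPM in shNT and 18 ± 1.2 TPM in shGLUD1 (-1.33); XPC, SESN1 and RRM2B rose (1.18, 1.13 and 1.04, rescaled 0.57, 0.71 and 0.56). RRM2B did not pass after rescaling (adjusted p = 0.116) or without shGLUD1 replicate 2 (0.56, 0.0861), and none of these 3 passed with length and GC trends removed (adjusted p = 0.0783, 0.296 and 0.392).

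Markers of kidney epithelium and of other cell types were read to look for RNA of other cells. Of 7 kidney epithelial markers, 4 fell and 2 rose, 5 and 1 after rescaling (median -1.03 from all genes, camera adjusted p = 0.00345; adjusted p = 0.486 with an estimated correlation). KRT7, a keratin, was at 104 ± 9.5 TPM in shNT and 41.3 ± 2.1 TPM in shGLUD1 (-1.31), AQP1 and KRT18 fell (-1.18 and -0.64), and MME rose (1.40). KRT18 passed narrowly (adjusted p = 0.0425) and did not without shNT replicate 1 (0.24), shNT replicate 2 (0.112), shGLUD1 replicate 1 (0.0794) or shGLUD1 replicate 2 (0.0538), each an adjusted p. At a mean of at least 5 TPM the call on the kidney list was lost (adjusted p = 0.106). Of 5 leukocyte markers, 4 rose and none fell on TPM, and none passed in either direction after rescaling by limma (camera adjusted p = 0.4); CD74 and CD68 were 0.59 and 0.56 on TPM and -0.17 and -0.20 rescaled, and CSF1R and CD3D were 1.10 and 0.90 (0.51 and 0.55 rescaled). CD3D did not pass without shNT replicate 2 (0.67, 0.149 as the adjusted p). Of 11 fibroblast and pericyte markers, 8 rose and 1 fell (rescaled 3 and 1, camera adjusted p = 0.943), with TAGLN lower (-2.18) and ACTA2, COL1A2 and THY1 higher (1.75, 1.40 and 1.30). The endothelial and red cell lists had 1 measured gene each and were not tested as lists: ENG was 1.06 on TPM and 0.36 rescaled, which did not pass, and HBG2 was -0.47 on TPM, which did not pass, and lower after rescaling (-0.91) and without shGLUD1 replicate 1 (-0.80, 0.0293 as the adjusted p).

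In all, camera called 14 of 31 lists, 6 higher and 8 lower relative to other genes. With an estimated correlation it called none, the lowest adjusted p being 0.486. Lists estimated below the preset 0.01 lost their calls too: mitochondrial ribosomal proteins (-0.006), oxidative phosphorylation (-0.006) and kidney markers (-0.13). Higher correlation does not account for those losses. This version has little power with 2 libraries per group, so it decides nothing against a call. Counts adjusted over the list alone equalled those over all genes wherever no second count is given. List median and camera direction differed in sign relative to all genes for ribosome biogenesis, lysosome and autophagy, proteasome and leukocyte markers, where the median lay below all genes and camera pointed up, and for glutamine, glutamate and proline metabolism, p53 targets and interferon-stimulated genes, where the reverse held. Among lists called lower, the medians of NRF2 targets (0.29) and oxidative phosphorylation (0.16) were above 0 on TPM, as was that of mitochondrial ribosomal proteins, and so were the means of these 3 (0.13, 0.23 and 0.18). Some settings that kept a call moved the list median relative to all genes by over 1.5 times. Without a filter on low values, the median relative to all genes was -0.37 for the unfolded protein response, -0.19 for kidney markers, 0.73 for the TCA cycle, 0.69 for glycolysis, 1.12 for S phase, 0.70 for extracellular matrix and 1.00 for mitochondrial mRNAs. That setting tested 24169 genes, and the added low genes lowered the median of all genes. The unfolded protein response, glycolysis, S phase and mitochondrial mRNA lists shifted by the same amount. Their own medians did not move, so their effects neither shrank nor grew. Kidney, TCA cycle and extracellular matrix lists shifted by other amounts. Quantile normalization gave -0.53 for the unfolded protein response, 0.67 for glycolysis and 0.95 for mitochondrial mRNAs, which were at 1.00 with length and GC trends removed. Mitosis was at 1.66 with a pseudocount of 0.1 TPM and 1.60 at a mean of at least 5 TPM, and glycolysis at 0.16 with that pseudocount and 0.15 without shNT replicate 2.

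Fold changes followed transcript length. Across 12258 genes with a known length, Spearman's rho between length and the log2 fold change was 0.39, against 0.01 for the difference within the shNT pair and 0.29 for that within the shGLUD1 pair, where genes are not independent replicates. For GC content rho was -0.20 between groups, -0.13 within the shNT pair and -0.42 within the shGLUD1 pair. Short RNAs that are mostly not polyadenylated differed between the groups: 8 of 8, picked after their values were seen, were lower in shGLUD1 (median -3.87). The median log2 fold change was -0.01 in the shortest of 10 groups of transcripts, of 78 to 930 nt, and 0.96 in the longest, of 6798 to 37852 nt. With length and GC trends removed, 5636 genes changed, 2866 higher and 2770 lower, and 1376 changed at least 2-fold; 2832 of the higher and 897 of the lower genes kept their direction and call, and 150 of the higher became lower. GLUD1 was then at -0.94 (SE 0.12, limma adjusted p = 0.00221).

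**Figure D3:**
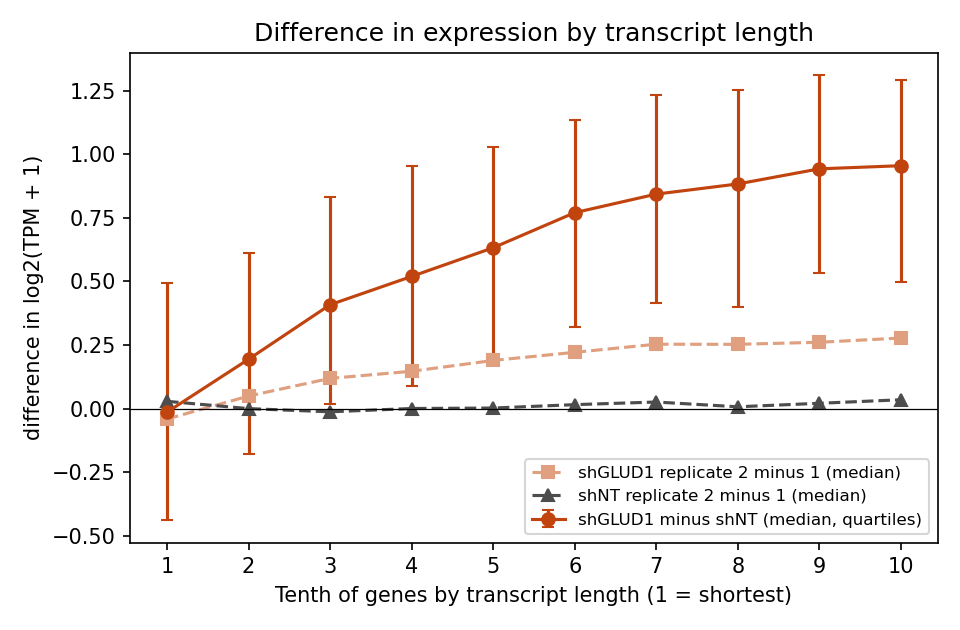
Difference in log2(TPM + 1) against 10 groups of genes by transcript length, from shortest (1) to longest (10). Circles give the median and quartiles of shGLUD1 minus shNT, which climb from -0.01 to 0.96; squares and triangles give the median of replicate 2 minus replicate 1 within shGLUD1 and within shNT.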

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

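Of the alternatives, removal of length and GC trends, the restriction to coding genes and the omission of ribosomal protein genes were added after seeing the data. The count of changed genes, 8078, stayed within 1.5 times under every alternative run, but its split did not. Genes higher in shGLUD1 numbered 4676 at a mean of at least 5 TPM, where fewer genes were tested, 2910 with median-ratio rescaling, 2938 with quantile normalization and 2866 with length and GC trends removed; genes lower numbered 3491, 2764 and 2770 in the last 3. Genes changed at least 2-fold numbered 2474, 2084, 1645 and 1376 in the same order. Rescaling and normalization set the typical gene to no change by construction, which accounts for the even split. GLUD1, at -0.11 on TPM, was -0.83 (adjusted p = 0.00233), -0.75 (0.00757) and -0.94 (0.00221) under these 3. The lowest within-group r, 0.985, was 0.972 with a pseudocount of 0.1 TPM, 0.990 without a filter, 0.988 with trends removed and 0.991 for coding genes, and the cause was not tested.

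With each library left out in turn, the lone library of its group being assumed to vary like the other pair, changed genes numbered 6244 to 8063, higher 5543 to 7103, lower 661 to 960 and 2-fold 3055 to 4641. GLUD1 ranged from -0.37 to 0.15, above 0 without shGLUD1 replicate 1 only. The cytosolic ribosomal protein median ranged from -1.22 to -0.92 and that of ATF4 targets from -0.80 to -0.76, relative to all genes, but other settings moved them further: -0.29 for ribosomal proteins under quantile normalization, and -0.61 and -0.33 without a filter. Without a filter it was the median of all genes that moved, and not that of either list. Uncalled lists crossed 0: glutamine, glutamate and proline metabolism (-0.16 to 0.15), cholesterol synthesis (-0.033 to 0.11) and leukocyte markers (-0.13 to 0.035). Libraries of the same number did not deviate together (1 correlation across genes, 0.04, the same for both numbers by construction). The fit with the replicate block changed 8456 genes, with GLUD1 at -0.11. Of 31 lists that fit lost oxidative phosphorylation (camera adjusted p = 0.0856) and gained amino acid transporters (0.0322), aminoacyl-tRNA synthetases (0.0162) and translation factors (0.0408).

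All 14 called lists lost their call with an estimated correlation, among them ribosomal proteins (-1.04, adjusted p = 0.486) and ATF4 targets (-0.76, 0.794). With 2 libraries per group that version has little power and decides nothing against a call. Fry, which tests a list against 0, lost ATF4 targets (-0.13, adjusted p = 0.0825) and the unfolded protein response (-0.18). Fry called 4 lists higher whose median lay below all genes: mitochondrial ribosomal proteins (0.10, adjusted p = 0.0357) and oxidative phosphorylation (0.16, 0.0357), which camera called lower, and the uncalled proteasome (0.27, 0.0494) and histones (0.39, 0.0357). It also called fibroblast and pericyte markers (0.84, 0.0406) and interferon-stimulated genes (0.91, 0.0494) higher, which camera did not call. Medians were also above 0, without a call, for ribosome biogenesis (0.53), amino acid transporters (0.33), lysosome (0.55), NRF2 targets (0.29), NF-kB (0.47), immediate early genes (0.48) and leukocyte markers (0.59). The direction of a list is the sign of its median relative to all genes, a rule chosen after camera's direction was seen to turn for uncalled lists. Not all such medians lay near 0: camera pointed up for the proteasome (-0.35) and down for interferon-stimulated genes (0.28). Elsewhere medians changed side, and except without a filter the cause was not tested. The glutamine, glutamate and proline list did so with a pseudocount of 0.1 TPM (-0.027), at a mean of at least 5 TPM (-0.011), rescaled (-0.029), under quantile normalization (-0.022), with trends removed (-0.065), for coding genes (-0.046) and without ribosomal protein genes (-0.0031). Translation factors did with the lower pseudocount (-0.019) and rescaled (-0.035). Without a filter, so did ribosome biogenesis (0.34), lysosome (0.32), proteasome (0.080) and immediate early genes (0.18). The added low genes had lowered the median of all genes there. The proteasome list shifted by the same amount as the ribosomal protein list, so its own median did not move. At a mean of at least 5 TPM, so did p53 targets (-0.11) and histones (0.25). Quantile normalization turned ribosome biogenesis (0.081), oxidative phosphorylation (0.034), cholesterol (-0.030), lysosome (0.10), proteasome (0.13) and leukocyte markers (0.33). Trend removal turned cholesterol (-0.037), histones (0.49), leukocyte (0.27) and fibroblast markers (-0.052). Of the other 137 named genes, CD74 (-0.17) and CD68 (-0.20) changed sign, both after rescaling. Over all named genes and alternatives, 57 results lost and 6 gained their call with the direction kept, and over lists 38 lost and 23 gained it. Since TPM keep no depth, how far depth limits low genes is unknown.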

Other observations

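The gene groups in this and the next paragraph, and the tests of explanations that follow them, were chosen after the data were seen, while median-ratio rescaling and the heat shock list were fixed before; the p-values here describe groups picked for their values. Short RNAs that are mostly not polyadenylated were lower in shGLUD1 in 8 of 8 genes picked (median log2 fold change -3.87, camera adjusted p = 4.2e-19; adjusted p = 0.0625 with an estimated correlation). The 7SK RNA gene RN7SK went from 581 ± 68.4 to 27.2 ± 4 TPM (mean ± SD, n = 2), RMRP, the RNA of RNase MRP, from 276 ± 4.3 to 9.77 ± 7.1 TPM, and SNORD3A, the U3 small nucleolar RNA, from 419 ± 17.1 to 16.5 ± 0.64 TPM. RN7SK and SNORD3A belong to families with many copies, so the split between loci is uncertain for them. Of 16 host genes of small nucleolar RNAs, 12 were lower and 2 higher on TPM (median -1.12, camera adjusted p = 1.0e-14; adjusted p = 0.0625 with an estimated correlation), and 12 lower and none higher with length and GC trends removed (median -1.41). GAS5 went from 966 ± 127 to 333 ± 22.6 TPM, SNHG15 from 176 ± 3.1 to 30.8 ± 3.3 TPM and ZFAS1 from 735 ± 55.7 to 326 ± 6.6 TPM, while SNHG3 went from 23.4 ± 5.5 to 56.2 ± 6.1 TPM.

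All 10 tubulin genes picked were higher (median 1.59, camera adjusted p = 4.9e-06; adjusted p = 0.343 with an estimated correlation), TUBA1B going from 847 ± 114 to 3676 ± 371 TPM and TUBB from 192 ± 19.6 to 947 ± 86 TPM; TUBB3 (0.49) was -0.26 after rescaling, and tubulin genes are similar in sequence, so the split of reads between them is uncertain. Of 9 secreted factors 4 were higher and 5 lower (median -0.98, camera adjusted p = 0.0101; adjusted p = 0.36 with an estimated correlation): CSF3 went from 40.1 ± 2.1 to 252 ± 15.7 TPM and STC1 from 8.87 ± 0.49 to 69.8 ± 16.4 TPM, against IL6 from 55.3 ± 7.4 to 24.3 ± 7.4 TPM, CCL26 from 59.6 ± 0.42 to 9.88 ± 1.2 TPM and IFNL1 from 52.5 ± 3.7 to 12.5 ± 0.57 TPM. Genes beside EGFR on chromosome 7 went both ways: SEC61G fell from 801 ± 30.9 to 480.5 ± 16.1 TPM and VOPP1 rose from 23.6 ± 2.8 to 48.2 ± 6.1 TPM (rescaled 0.26, which did not pass), while LANCL2, from 4.57 ± 0.53 to 6.81 ± 0.17 TPM, did not pass.

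The first pattern weighed is that 88.0% of changed genes were higher in shGLUD1 and that fold changes rose with transcript length. A smaller share of TPM in ribosomal protein transcripts is not the whole cause: with these genes left out and TPM set to 1000000 over the rest, 81.4% of changed genes were still higher and the median shift was 0.49 in place of 0.63. With length and GC trends removed 5636 genes still changed, but this cannot exclude such bias as the whole cause. The longest coding transcript need not be the one expressed (RPS29 was given 7062 nt and RPL14 7072 nt). Bias that is no smooth function of that length stays in. Of the 5636 genes 50.9% were higher, and rho with length was 0.0059, which the correction fixes by construction. The part of length or GC bias in the excess of higher genes therefore stays open. Also open is how much of the shift is a change in RNA content, RNA quality or library preparation, because TPM hold only shares. Within the shGLUD1 pair differences also followed length (rho 0.29) and GC content (rho -0.42). The short, mostly not polyadenylated RNAs were lower in 8 of 8, but these were picked for their values. Replication-dependent histone mRNAs, fixed in advance as a library check, were not called (8 higher and 3 lower on TPM, 4 and 7 rescaled, 7 and 3 with trends removed). That check decides nothing, because S phase genes rose, and a rise of histone mRNAs with replication could hide a loss. A biological effect of the hairpin on the share of long or weakly expressed transcripts was not tested.

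The second is that GLUD1 TPM was not lower in both labelled libraries. GLUD2 and GLUD1 pseudogenes summed to at most 3.885% of GLUD1 TPM in a shGLUD1 library. That cannot exclude reads of these copies counted with GLUD1, since such reads would be missing from the copies' own entries. An exchange of 1 library of each group does not account for it, as the lowest r within a group exceeded the highest between groups by 0.0394. The shift in composition that raised most genes cannot be told apart from a weak effect of the hairpin on the mRNA. Rescaling moves all genes nearly alike, so the -0.83 it gave for GLUD1 followed from that step and decides nothing. Composition, a weak effect of the hairpin and reads of copies all remain open, and protein was not analysed here.

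The third is the lower level of heat shock transcripts. Neither TPM scaling nor a smooth trend with annotated length or GC content accounts for it. A factor per library moves all genes nearly alike, while the heat shock median lay -1.66 from all genes. With the trends removed that median was -1.65, against -1.04 on TPM. A weaker stress response in GLUD1-targeted cells is one hypothesis, and a difference in handling or in the depth of starvation between the groups is another. The 2 cannot be told apart: the labels do not tell how the groups were handled, the axis separating the groups held 88.4% of the variance, and no label or library crosses it. Fed cells, or a second hairpin, were not analysed here.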
